A study of Mus musculus with 14 samples.

How the data were processed

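RNA was sequenced from wild-type C57BL/6 mouse Tim-4-positive peritoneal macrophages and from apoptotic cells (ACs, irradiated thymocytes). Per the labels' protocols, total RNA was extracted with RNAzol, treated with DNase, depleted of ribosomal RNA from 1 ug, made into TruSeq libraries and sequenced for 50 cycles from a single end on a HiSeq 4000. Base calling with CASAVA 2.7, trimming with cutadapt 1.1, quantification with kallisto 0.43.3 and testing with sleuth are named per the submitters' processing notes, which give the genome as GRCm38.

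The deposited files give, per library and transcript, an estimated count, which the authors did not normalise, and TPM, a length-scaled relative abundance, as deposited by the authors from kallisto, per the file headers. Estimated counts were summed per gene and rounded. The 11 libraries outside experiment 1 list 96626 Ensembl transcripts, of which 95213 (98.5%) matched the GENCODE annotation of GRCm38, giving 31956 genes and 99.3% to 99.5% of the counts. The 3 libraries of experiment 1 list 344513 targets with GenBank accessions, of which 608 could be named, so they entered no fit. The planned experiment term then dropped out, and the ex vivo group holds 1 library, which is assumed to vary like the other groups. Totals were 17237469 to 34016498 estimated counts in the 11 libraries. Intervals and floors of 3 counts per library cover counting error only. The p-values measure only the spread between these libraries, because the labels do not say which came from separate animals or cultures.

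Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (17578 genes kept), a robust quasi-likelihood fit of the 6 groups with 5 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. The standard error was taken as the absolute log2 change divided by the square root of F. CPM values use the TMM-scaled library sizes. The 6 comparisons were 60 h of culture against ex vivo, 2 h against ex vivo, 60 h against 2 h, ACs at 2 h, ACs at 60 h, and the difference between the changes with ACs. The comparison of 60 h with 2 h was added after the structure of the files was seen. The groups, tests, gene lists, named-gene rule and most alternatives were set before the data were examined.

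The AC RNA share of an exposed library was the median over thymocyte markers of its excess over unexposed macrophages divided by the excess of ACs alone, using markers with at least 20 CPM in ACs alone and at least 10 times the unexposed level. The share was taken on TMM-scaled levels and is larger than the share of counts. A rise beyond mixing had to pass against both the unexposed macrophages and ACs alone. A fall beyond mixing had a log2 change whose value plus 2 SE lay below the bound set by the highest share (-0.33 at 2 h and -0.43 at 60 h), or also lay below ACs alone. The expected mixture, added after the data were seen, compares exposed libraries with unexposed and AC-alone counts combined at the estimated share, and at 0.8 and 1.2 times it.

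The 23 gene lists covered the peritoneal macrophage signature, macrophage transcription factors, AC recognition, nucleic acid sensing, surface Toll-like receptors, interferon-stimulated, inflammatory, feedback regulator, LXR and PPAR, cholesterol synthesis, lysosome and phagosome, tissue remodelling, glycolysis and hypoxia, cell cycle, immediate early and stress, p53 target and MHC class II genes. They also covered markers of thymocytes, B cells, mast cells, neutrophils, mesothelium and fibroblasts, and monocytes and dendritic cells. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 23 lists of a comparison. In the fit of all groups, calls that hold with an estimated correlation number 30 of 50, and in fits of the compared groups alone 2 lists pass with an estimated correlation, the inflammatory and cell cycle lists for the difference. The 30 are the peritoneal macrophage, cholesterol, lysosome, remodelling and cell cycle lists at 60 h, and the interferon, inflammatory and feedback lists at 2 h. Between 60 h and 2 h they are those 3 and the peritoneal macrophage, cholesterol, lysosome, cell cycle and immediate early lists. With ACs they are the AC recognition, lysosome, p53 and thymocyte lists at both times, the inflammatory, feedback and cell cycle lists at 60 h, and the same 3 for the difference. Against the expected mixture, the camera adjusted p at 2 h and 60 h was 0.416 and 0.527 for AC recognition, 0.820 and 0.243 for lysosome, 0.840 and 0.220 for p53 and 0.585 and 0.837 for thymocyte genes, so camera called none of these 4 lists. With fry in 1 direction, AC recognition and lysosome passed downward at 2 h (both fry adjusted p = 0.0346). At 60 h lysosome passed downward (fry adjusted p = 0.00919) and p53 upward (fry adjusted p = 0.00939), so changes beyond AC RNA stay open for these 3 lists. The thymocyte result is no test, since the share was set from markers of that list.

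Genes are named by 3 rules. Rule a takes, per comparison, the 5 largest rises and 5 largest falls past the test with at least 10 CPM in the higher group and 1 direction in every pair of libraries, beyond mixing where ACs are compared, and skips genes without an approved-style name. Rule b takes up to 4 members with the smallest adjusted p from each list described. Rule c always takes Gata6, Timd4, Klf2, Klf4, Tlr9, Mertk and Axl. Other genes were named after their values were seen. Some genes that these rules pick are not reported here. The Hgs records overlap, and reads of pseudogenes can be shared with their parent genes.

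Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in 2 libraries, a transcript length offset, limma on log2(TPM + 1), fits of the compared groups alone, a replicate block, each library left out in turn, genes lower in ACs alone, other share estimates, and camera with an estimated correlation or fry for lists. The steps were tested on simulated data from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold among 17578. All 6 groups were given the same mean per gene, the average of the macrophage groups, and 59 to 98 genes were called. The real comparisons called far more genes, which loosens the adjusted cut, and differ in composition. The shares below therefore do not carry over to them directly. The share of 4-fold changes recovered was 45% for 60 h against ex vivo, 56% for 2 h against ex vivo, 63% for 60 h against 2 h, 62% for ACs at 2 h, 55% for ACs at 60 h and 46% for the difference. For 2-fold changes it was 19%, 19%, 18%, 28%, 27% and 8% in that order. Unchanged genes made up 9.86%, 14.8%, 3.57%, 8.16%, 9.89% and 8.47% of the calls, above the nominal 5% in 5 of the 6. In simulated mixtures with 200 genes raised 4-fold above both pools, rises beyond mixing were recovered for 73% at 2 h and 63% at 60 h, with 5 and 6 unchanged genes called, and 18 and 20 unchanged genes were called against the mixture. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.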

Results

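RNA was measured by sequencing in Tim-4-positive peritoneal macrophages of wild-type C57BL/6 mice, the tissue-resident phagocytes of the peritoneal cavity, in 14 libraries of 6 groups. Macrophages were taken immediately ex vivo or kept in complete RPMI medium for 2 h or 60 h. Further libraries came from 2 h and 60 h macrophage cultures with apoptotic cells (ACs, irradiated thymocytes), and from ACs alone. The labels place 1 ex vivo and 2 cultured 60 h libraries in each of 2 experiments, and the other 4 groups hold 2 libraries each. How long the macrophages and ACs were together is not given in the labels. The 3 libraries of experiment 1 held 46043404 to 56358259 estimated counts and could not be joined to the others, which held 17237469 to 34016498, so all comparisons rest on 11 libraries with 1 ex vivo library. That library is assumed to vary like the other groups, and the p-values measure only the spread between these libraries, since the labels do not say which came from separate animals or cultures. Levels below are CPM, counts relative to the TMM-scaled library size, given as mean ± SD with n = 2, or as a single value for the ex vivo library. Fold changes are on the log2 scale with their standard error (SE). Coordinates are on GRCm38.

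The first comparison asked what changes when resident macrophages are kept away from their tissue for 60 h. Genes that mark peritoneal macrophages fell. Gata6, the transcription factor that defines this population (chromosome 18, 11052064 to 11085635), went from 136 CPM ex vivo to 18.9 ± 2.48 (SD, n = 2), a log2 change of -2.84 ± 0.24 (SE). Timd4, which encodes the Tim-4 phosphatidylserine receptor used to identify these cells (chromosome 11, 46810800 to 46844332), went from 486 CPM to 31.6 ± 3.49 (SD, n = 2), a log2 change of -3.95 ± 0.24. Klf2 and Klf4, zinc-finger transcription factors of quiescent myeloid and endothelial cells, fell with log2 changes of -4.97 ± 0.30 and -3.52 ± 0.29. The edgeR adjusted p-values of these 4 genes lay between 3.05e-08 and 8.24e-07.

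Of 25 peritoneal macrophage signature genes measured, 22 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 7.51e-17). F5, coagulation factor V, fell with a log2 change of -4.11 ± 0.17, from 3363 CPM to 195 ± 14.7 (SD, n = 2). Ltbp1, a latent TGF-beta binding protein, had a log2 change of -3.48 ± 0.15, and Garnl3 and Aspa had changes of -4.38 ± 0.20 and -4.06 ± 0.21. Cell cycle genes fell as well, 26 of 29 over all genes and 28 adjusted over the list alone, with 0 rises (camera adjusted p = 2.43e-20). Among them Top2a, the topoisomerase of dividing cells, went from 220 to 15.0 ± 2.07 CPM (SD, n = 2). Kif11, a spindle motor, Rrm2, a subunit of ribonucleotide reductase, and Ccnd1, cyclin D1, had log2 changes of -4.07 ± 0.18, -4.42 ± 0.27 and -5.85 ± 0.30.

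Genes of the lysosome and of cholesterol synthesis moved the other way. Of 29 lysosome and phagosome genes, 20 rose and 0 fell, and 22 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.83e-10). Gpnmb, a lysosomal membrane glycoprotein (chromosome 6, 49036546 to 49070929), went from 17.2 CPM to 2842 ± 107 (SD, n = 2), a log2 change of 7.37 ± 0.33. The cathepsin genes Ctsd and Ctsb and the lysosomal cholesterol transporter gene Npc1 had changes of 2.62 ± 0.18, 2.26 ± 0.17 and 2.04 ± 0.15. Of 25 cholesterol synthesis genes, 15 rose and 0 fell under either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 9.83e-10). Hmgcs1, which makes HMG-CoA, rose by 2.67 ± 0.23, with Cyp51 at 2.96 ± 0.31, Fdps at 2.26 ± 0.25 and the sterol sensor partner Insig1 at 2.08 ± 0.19. Of 25 tissue remodelling genes, 13 rose and 7 fell (14 and 7 adjusted over the list alone), with camera adjusted p = 6.09e-04. Examples are the matrix metalloproteinase genes Mmp14 and Mmp12, at 7.59 ± 0.24 and 6.07 ± 0.24, and the growth factor gene Pdgfb at 4.90 ± 0.23.

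Receptors that recognise ACs went in both directions, 11 of 29 measured genes up and 8 down with the same counts adjusted over the list alone (camera adjusted p = 0.311). The integrin genes Itgb5 and Itgax rose by 7.60 ± 0.32 and 6.30 ± 0.46 and the bridging ligand gene Gas6 by 4.28 ± 0.28, whereas Itgb3 fell with a change of -5.45 ± 0.40. Mertk and Axl, receptor kinases that bind AC-bound ligands, rose by 0.98 ± 0.15 and 1.26 ± 0.18. Macrophage transcription factor genes also split, with 10 of 21 up and 9 down under both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.790). Bhlhe41 and Runx1 rose by 4.78 ± 0.23 and 2.53 ± 0.17, while the median of this list was 0.06 and its mean -0.02. Of 24 nucleic acid sensing genes, 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.407). They were Tlr8 at 1.53 ± 0.18, Tbk1 at 1.1 ± 0.16, Tlr7 at 0.83 ± 0.15 and Samhd1 at -0.75 ± 0.14, with 1 further rise. Tlr9, the endosomal sensor of unmethylated DNA, stood at 0.645 CPM ex vivo and 7.75 ± 0.70 (SD, n = 2) at 60 h, which did not pass the test (log2 change 3.58 ± 1.66, edgeR adjusted p = 0.199).

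Sterol-responsive LXR and PPAR target genes included 8 rises and 3 falls among 25 (9 and 3 adjusted over the list alone), among them Apoe at 2.57 ± 0.17, Fabp5 at 2.84 ± 0.19, Abca1 at 1.88 ± 0.14 and Angptl4 at 4.16 ± 0.46. That list had a camera adjusted p = 0.0423, and an adjusted p = 0.234 in camera with an estimated correlation. Of 24 records of glycolysis and hypoxia genes, 8 rose and 4 fell (9 and 6 adjusted over the list alone), led by Tpi1 at 1.71 ± 0.17, Slc2a1 at 2.16 ± 0.22, Aldoa at 1.23 ± 0.17 and Hk2 at 1.35 ± 0.19 (camera adjusted p = 0.365). Of 12 genes for antigen presentation on MHC class II, 2 rose and 4 fell (2 and 5 adjusted over the list alone). H2-Aa and H2-Eb1 fell with changes of -1.61 ± 0.15 and -1.38 ± 0.29, and the costimulator gene Cd86 rose by 1.27 ± 0.19. H2-Oa, with 0 counts ex vivo, was at least 8.22-fold higher at 60 h (camera adjusted p = 0.247 for the list).

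The largest single rises and falls included genes with no counts in 1 of the groups, for which a floor of 3 counts per library gives a bound. Mmp13, an interstitial collagenase (chromosome 9, 7272514 to 7283331), had 0 counts ex vivo and was at least 256-fold higher at 60 h, at 33.0 ± 2.66 CPM (SD, n = 2). Pdpn, which encodes podoplanin, and Myom1 were at least 116-fold and 98.2-fold higher. Ms4a7 rose by 8.11 ± 0.41 on the log2 scale. Ms4a14 had 1 count ex vivo, so its ratio was 373-fold with a 95% counting interval of 66.9 to 14800. Among the falls, Asz1 and Hgd had 0 counts at 60 h and were at least 374-fold and 117-fold lower. Lyve1, a hyaluronan receptor gene of tissue macrophages and lymphatic endothelium, Vmn2r26 and Plekha6 had changes of -9.05 ± 0.44, -8.55 ± 0.41 and -8.43 ± 1.24.

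Of the markers of other cells, few genes passed the test and no list was called. The mast cell genes Hdc and Kit fell, 2 of 8 measured with 0 rises, also adjusted over the list alone (camera adjusted p = 0.101). Hdc, which makes histamine, went from 84.1 CPM to 2.42 ± 0.91 (SD, n = 2), while Kit had 2 counts at 60 h and a ratio of 11.3-fold (95% counting interval 2.35 to 108). The summed level of the mast cell markers was 86.7 CPM ex vivo, 3.67 and 2.86 CPM at 60 h, and 171 and 223 CPM at 2 h. Cma1, at 1.38 CPM ex vivo with 0 counts at 60 h, and Ms4a2, at 0.215 CPM ex vivo, did not pass the test. Of 10 neutrophil genes, Mmp8 and S100a8 rose by 6.33 ± 1.25 and 3.79 ± 1.12 and 0 fell, also adjusted over the list alone (camera adjusted p = 0.723). Lcn2, at 2.75 CPM ex vivo and 0.436 CPM at 60 h, and Ltf, near its floor, did not pass. Of 14 monocyte and dendritic cell genes, 2 rose and 5 fell (3 and 5 adjusted over the list alone), with Cd209a at 3.27 ± 0.33, Ccr2 at -3.04 ± 0.32, Irf4 at -2.60 ± 0.26 and Clec10a at -2.63 ± 0.42 (camera adjusted p = 0.311). Of 12 B cell genes 1 rose and 0 fell (camera adjusted p = 0.790), and of 14 mesothelial and fibroblast genes 0 passed the edgeR test in either direction, with 1 at an unadjusted p of 0.05 and 1 rise in the fit of these groups alone (camera adjusted p = 0.788), with the same counts adjusted over the list alone. Over all 17578 genes tested, edgeR's quasi-likelihood test called 1617 genes higher and 1537 lower at an adjusted p of 0.05, of which 1159 and 994 changed at least 2-fold. Limma on log2(TPM + 1) called 1021 genes higher. The call of Kit was lost without 60 h replicate 1 of experiment 2 and that of S100a8 without 60 h replicate 2.

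**Figure D1:**
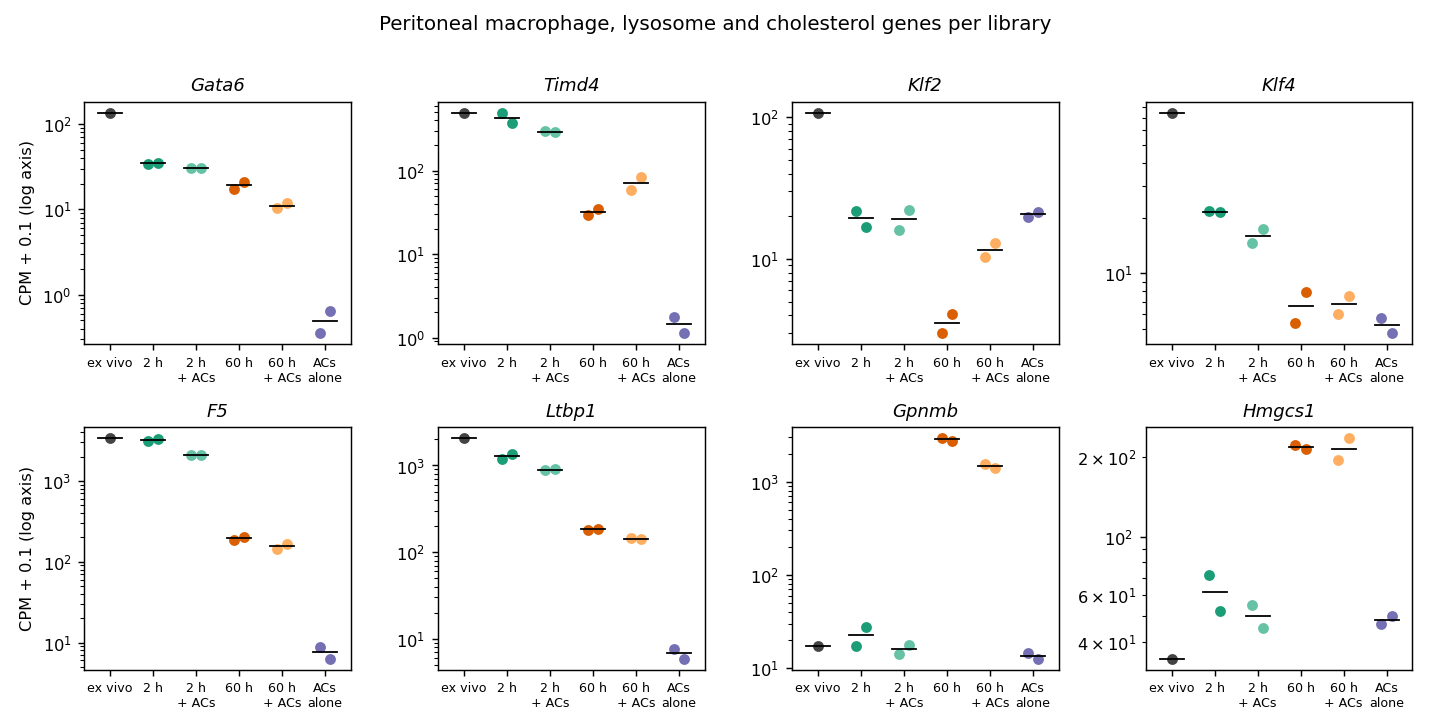
CPM + 0.1 on a log axis for 8 genes, with 1 point per library and a line at each group mean, for the ex vivo, 2 h, 2 h + ACs, 60 h, 60 h + ACs and AC-alone groups. Gata6 stood at 136 CPM ex vivo and 18.9 CPM at 60 h, and Gpnmb at 17.2 and 2842 CPM.

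The short culture was compared with the same ex vivo library. That library carries an experiment label and the 2 h libraries do not, so they may differ in more than time in culture. Genes of inflammation and of the interferon response stood higher at 2 h. Il1b, which encodes interleukin-1 beta (chromosome 2, 129364570 to 129371139), went from 2.54 CPM ex vivo to 488 ± 19.8 (SD, n = 2), a log2 change of 7.59 ± 0.22. Of 29 inflammatory genes measured, 21 rose and 0 fell, and 24 rose adjusted over the list alone (camera adjusted p = 8.30e-16). The adhesion receptor gene Icam1 and the cytokine genes Il1a and Tnf rose by 4.70 ± 0.17, 5.42 ± 0.24 and 4.58 ± 0.24. Of 35 interferon-stimulated genes, 23 rose and 0 fell, and 24 rose adjusted over the list alone (camera adjusted p = 1.83e-11), including Oasl1 at 5.15 ± 0.36, Ifi205 at 5.12 ± 0.31, Ifih1 at 2.53 ± 0.20 and Parp14 at 2.45 ± 0.16.

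Regulators that restrain these responses rose too, 20 of 25 with 2 falls under both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 5.62e-10). Tnfaip3, a ubiquitin-editing enzyme that restrains NF-kappaB, Il1rn, the interleukin-1 receptor antagonist, and Tnip3 rose by 4.42 ± 0.18, 6.62 ± 0.31 and 5.61 ± 0.32. Dusp1, a phosphatase that restrains MAP kinases, fell with a change of -3.0 ± 0.16. Immediate early and stress genes split, with 13 of 27 up and 7 down (13 and 10 adjusted over the list alone; camera adjusted p = 0.438). Egr2 and the haem oxygenase gene Hmox1 rose by 5.21 ± 0.25 and 4.35 ± 0.26, and Jun fell with a change of -2.98 ± 0.22. Of the 25 peritoneal macrophage signature genes, 10 fell and 4 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.133). Tgfb2, Garnl3 and the retinoic acid receptor gene Rarb had changes of -2.76 ± 0.19, -1.92 ± 0.19 and -3.44 ± 0.37, and Thbs1, thrombospondin 1, rose by 2.51 ± 0.18 to 64160 ± 8322 CPM (SD, n = 2). Gata6, Klf2, Klf4 and Mertk fell with changes of -1.97 ± 0.24, -2.48 ± 0.28, -1.79 ± 0.28 and -0.90 ± 0.14. Timd4 stood at 431 ± 88.5 CPM (SD, n = 2) with a change of -0.17 ± 0.24, Axl at 69.6 ± 5.25 CPM with -0.20 ± 0.17, and Tlr9 at 1.13 ± 0.48 CPM with 0.80 ± 1.49, none past the test.

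By the size of the change, Mmp13, the plasminogen activator gene Plat, Gng4 and the lipase gene Lipg had 0 counts ex vivo and were at least 167-fold, 119-fold, 104-fold and 84.3-fold higher at 2 h. Mefv, which encodes pyrin, had 1 count ex vivo and a ratio of 1160-fold (95% counting interval 208 to 45900). The largest falls were those of Cyp26a1, a retinoic acid hydroxylase gene, at -6.58 ± 2.01, Lpar5 at -5.90 ± 0.83, Cbx8 at -4.70 ± 0.79, Ubash3a at -4.70 ± 0.31 and Trib2 at -4.46 ± 0.27. Ubash3a and Trib2 were also abundant in ACs alone, at 66.8 and 118 CPM, and the summed thymocyte markers stood at 74.9 CPM ex vivo, and at 51.1 and 77.3 CPM in the 2 h libraries, on either side of it. Over all genes, edgeR called 2025 higher and 1982 lower, with 1283 and 1358 of them changed at least 2-fold. Limma called 1000 genes higher, and fits of the compared groups alone called 1256 higher and 1089 lower. The call of Cyp26a1 (edgeR adjusted p = 0.0443) was lost in DESeq2, with a transcript length offset and without 2 h replicate 2.

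The 60 h and 2 h cultures without ACs were then compared directly, a comparison added after the structure of the files was seen. Only the 60 h libraries carry an experiment label, so these sets too may differ in more than time in culture. The inflammatory and interferon-stimulated genes stood lower at 60 h than at 2 h. Of 29 inflammatory genes, 20 were lower and 1 higher (21 and 1 adjusted over the list alone; camera adjusted p = 8.35e-12), with Cxcl1, Cxcl2, Il1a and Il1b at -5.14 ± 0.17, -4.56 ± 0.15, -3.84 ± 0.16 and -3.77 ± 0.13. Of 35 interferon-stimulated genes, 25 were lower and 1 higher (28 and 1 adjusted over the list alone; camera adjusted p = 2.34e-12), with Oasl1 at -5.35 ± 0.26, Ifi205 at -4.79 ± 0.22, Gbp2 at -3.21 ± 0.15 and Parp14 at -2.28 ± 0.12. Of the lysosome and phagosome genes, 19 of 29 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 1.36e-07), with Gpnmb at 7.0 ± 0.23, Ctsd at 2.45 ± 0.14, Ctss at 2.09 ± 0.14 and Npc1 at 1.77 ± 0.11. Against ex vivo, 10 of 29 inflammatory genes stood higher at 60 h and 4 lower (camera adjusted p = 0.085). Of 35 interferon-stimulated genes, 5 stood higher at 60 h than ex vivo and 7 lower (camera adjusted p = 0.788).

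Other large rises from 2 h to 60 h were those of the collagenase gene Mmp8 at 6.50 ± 0.92, the proton pump subunit gene Atp6v0d2 at 6.31 ± 0.69, Slc16a9 at 6.11 ± 0.44 and Cd300c2 at 5.85 ± 0.41. Plat, Lipg and Hgd had 0 counts at 60 h and were at least 147-fold, 104-fold and 104-fold lower than at 2 h, and Lyve1 and Vmn2r26 had changes of -7.89 ± 0.41 and -7.54 ± 0.39. Between these times edgeR called 2532 genes higher and 2603 lower, 1607 and 1313 of them at least 2-fold. Limma on log2(TPM + 1) called 2178 higher and 1524 lower.

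Macrophage libraries exposed to ACs also held AC RNA, so the share was estimated before their changes were read. Over 29 thymocyte markers the median share on TMM-scaled levels was 18.9% and 20.3% in the 2 libraries at 2 h. Over 28 markers it was 25.7% and 26.0% at 60 h. Without TMM scaling, as shares of the counts, these were 12.9%, 14%, 18.3% and 18.1%. The TMM-scaled values are larger because the TMM scaling factors of ACs alone, 1.406 and 1.412, exceed those of the exposed libraries, 0.954 to 1.004. If its weights sum to 1, a mixture can lower a macrophage gene by no more than the share of added RNA. It can then raise a gene no higher than the richer of its sources. Under that assumption, rises beyond mixing were those above the unexposed macrophages and also above ACs alone. Falls beyond mixing were those larger than the highest share allows or also below ACs alone. Non-negative least squares on the TMM-scaled levels gave unexposed RNA weights of 0.726 and 0.702 at 2 h and 0.8064 and 0.8225 at 60 h. The AC weights were 0.1945 and 0.2117 at 2 h and 0.2168 and 0.2238 at 60 h. On this scale the weights thus did not sum to 1. By these weights, the bound and the expected mixture are too high for macrophage genes at 2 h and too low at 60 h. Changes against the mixture are thereby shifted down at 2 h and up at 60 h.

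**Figure D2:**
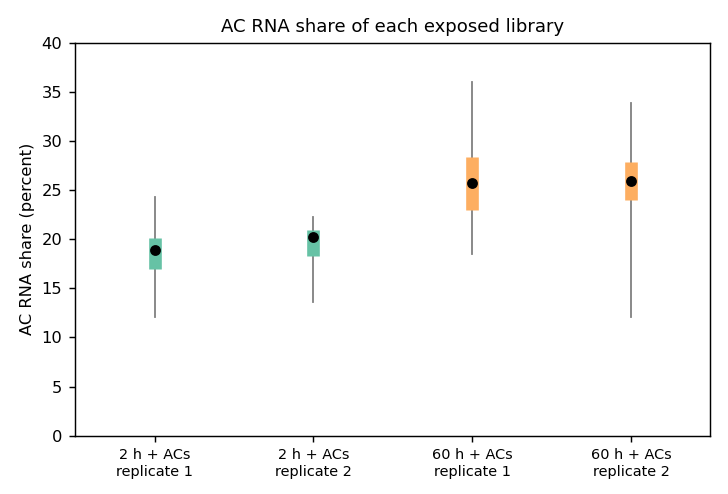
AC RNA share in percent, on TMM-scaled levels, for each of the 4 exposed libraries. The median over thymocyte markers is a point, the interquartile range a thick bar and the full range a thin line. The medians are 18.9% and 20.3% at 2 h and 25.7% and 26.0% at 60 h.

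At 2 h, the changes with ACs were mainly those of thymocyte transcripts. Of 31 thymocyte genes, 29 rose and 0 fell, and 30 rose adjusted over the list alone (camera adjusted p = 3.93e-38). Arpp21 went from 2.48 ± 0.05 to 197 ± 14.1 CPM (SD, n = 2 each) beside 978 ± 88.9 CPM in ACs alone, a log2 change of 6.31 ± 0.22. The T cell gene Cd28 and the nuclease gene Endou rose by 4.55 ± 0.16 and 6.55 ± 0.32. Of 20 p53 target genes, 9 rose and 0 fell (10 and 2 adjusted over the list alone; camera adjusted p = 1.55e-04), with Trp53inp1 at 2.37 ± 0.17, Polk at 1.67 ± 0.13, Phlda3 at 3.53 ± 0.31 and the apoptosis gene Bbc3 at 2.09 ± 0.22. All 4 were abundant in ACs alone, at 62.9 to 2042 CPM, and 0 of the 9 p53 targets that rose stood above the expected mixture of the 2 RNA pools in edgeR.

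Receptor genes for ACs stood lower in the exposed libraries, 11 of 29 with 0 rises, and 17 adjusted over the list alone (camera adjusted p = 1.71e-06). Compared with the expected mixture, 0 of the 29 rose or fell in edgeR (1 and 4 adjusted over the list alone, 1 and 7 at an unadjusted p of 0.05), the list median was -0.16 and the list was not called (camera adjusted p = 0.416). Against the unexposed macrophages, the fit of these groups alone called 3 falls and 0 rises. The integrin genes Itgav and Itgam had changes of -0.74 ± 0.12 and -0.61 ± 0.13, Gas6 -1.18 ± 0.21, Mertk -0.65 ± 0.12 and Axl -0.48 ± 0.14. The bound set by the highest share was -0.33, which is too lenient at 2 h by the least-squares weights. Axl (edgeR adjusted p = 0.0488) lost its call in 10 of 13 alternatives, and Mertk against the expected mixture had a change of -0.34 (edgeR adjusted p = 0.352). Timd4, Gata6, Klf2, Klf4 and Tlr9 had changes of -0.56 ± 0.20, -0.18 ± 0.20, -0.03 ± 0.24, -0.43 ± 0.24 and -0.70 ± 1.17, none past the test. Mertk also lost its call without 2 h + ACs replicate 2, and Itgam lost its call without either 2 h + ACs library. Gas6 lost its call with limma, in the fit of these groups alone and with the replicate block, and Itgav with the length offset and limma.

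Beyond mixing, 4 genes rose at 2 h, no more than the 5 unchanged genes called so in simulated libraries that held 200 changed genes. Naca, a gene of the nascent polypeptide complex, rose by 0.50 ± 0.13. Rises also included Rpl5-ps2 and Gm9794, named after their values were seen, which can share reads with near-identical ribosomal protein copies. Falls beyond mixing numbered 256, but only 9 of them (3.52%) also lay below the expected mixture. Most of these falls are thus not separated from AC RNA, and the simulation did not check falls. They were led by Arrdc3 at -1.29 ± 0.19, the purinergic receptor gene P2ry12 at -1.19 ± 0.28 and the creatine synthesis gene Gatm at -1.13 ± 0.23. Dnajb13 and the activation marker gene Cd83 followed at -1.12 ± 0.23 and -1.1 ± 0.15. Over all genes, edgeR called 1035 higher and 620 lower with ACs at 2 h, 803 and 23 at least 2-fold. The count of lower genes was 17 with limma, 112 without 2 h + ACs replicate 1 and 72 without 2 h + ACs replicate 2, and without the latter 687 genes were higher. Against the expected mixture, 7 genes stood higher and 13 lower at 2 h in edgeR. The 18 unchanged genes called against the mixture in that simulation are no like count. Its 145 recovered changes loosen the adjusted cut. The count of 4 rises beyond mixing became 10 without either 2 h library, 2 without either 2 h + ACs library and 7 without AC-alone replicate 2. Naca lost its call without 2 h replicate 1 or either 2 h + ACs library, P2ry12 without 2 h replicate 1 or 2 h + ACs replicate 2, Gatm without the latter and Dnajb13 without 2 h + ACs replicate 1.

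In the 60 h cultures, inflammatory genes stood higher with ACs than without. Il1b went from 35.8 ± 3.45 to 909 ± 39.9 CPM (SD, n = 2 each), a log2 change of 4.67 ± 0.13, with 3.04 ± 0.09 CPM in ACs alone. Cxcl1 and Cxcl2, neutrophil chemoattractants, rose by 4.37 ± 0.17 and 3.81 ± 0.15 and Il1a by 4.09 ± 0.17. Of 29 inflammatory genes, 15 rose and 0 fell, and 19 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.28e-10). Against the expected mixture, 14 of the 15 were higher in edgeR. Of 25 feedback regulator genes, 12 rose and 0 fell, and 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.04e-08). Nfkbiz, which encodes an inducible NF-kappaB cofactor, rose by 3.07 ± 0.14, Tnfaip3 by 1.47 ± 0.12 and the inhibitor gene Nfkbia by 1.34 ± 0.12. Socs1 rose by 4.22 ± 0.30, to 23.0 ± 4.75 CPM (SD, n = 2), but ACs alone held 153 ± 25.7 CPM.

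Surface Toll-like receptor pathway genes included 3 rises and 1 fall among 16 (3 and 5 adjusted over the list alone; camera adjusted p = 0.936, direction down against a median of 0.11 and a mean of 0.11). Compared with the expected mixture, 4 of these genes rose and 0 fell in edgeR (5 and 0 adjusted over the list alone), and the list was called up (camera adjusted p = 0.00191; adjusted p = 0.286 in camera with an estimated correlation). Tlr2, a receptor for bacterial lipoproteins, Cd14 and the signalling kinase gene Irak2 rose by 1.06 ± 0.12, 1.11 ± 0.22 and 0.52 ± 0.12, and Cd180 had a change of -0.79 ± 0.24, which was not beyond mixing (-0.36 against the expected mixture, edgeR adjusted p = 0.291). The call of Cd180 was lost without any 1 of the 4 libraries, that of Irak2 without 60 h replicate 1 of experiment 2 or 60 h + ACs replicate 2, and that of Cd14 without 60 h replicate 2 of experiment 2. Of 35 interferon-stimulated genes, 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.120). Ifi205 and the chemokine gene Cxcl10 rose by 2.75 ± 0.21 and 3.63 ± 0.54, and Usp18 and Ddx60 had changes of -1.51 ± 0.17 and -1.0 ± 0.17. Receptor genes for ACs included 4 rises and 9 falls among 29 (5 and 17 adjusted over the list alone; camera adjusted p = 0.00181). Compared with the expected mixture there were 4 rises and 1 fall in edgeR (4 and 4 adjusted over the list alone), and the downward list call was lost (camera adjusted p = 0.527, direction up against a median of -0.09). Among them Olr1, the oxidised LDL receptor gene, rose by 1.68 ± 0.18 and Itgb3 by 2.66 ± 0.35, with Cd300lb at -1.01 ± 0.13 and Pros1, which encodes protein S, at -0.77 ± 0.11.

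Cell cycle genes rose in 21 of 29 cases with 0 falls, and 24 rose adjusted over the list alone (camera adjusted p = 1.1e-14). Top2a, Kif11, Rrm2 and Ccna2 rose by 3.18 ± 0.13, 3.42 ± 0.16, 4.79 ± 0.25 and 2.57 ± 0.22. Top2a stood at 513 ± 16.8 CPM (SD, n = 2) in ACs alone, and 1 of the 21 genes, the proliferation marker Mki67, exceeded the expected mixture in edgeR. Timd4 rose by 1.16 ± 0.20 and by 1.57 against the expected mixture. Klf2 rose by 1.73 ± 0.25, though its change against the mixture was 0.54 (edgeR adjusted p = 0.222). Gata6 and Mertk had changes of -0.79 ± 0.21 and -0.77 ± 0.12, against mixture values of -0.37 and -0.34 that did not pass. Of 10 neutrophil genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.010, adjusted p = 0.0889 in camera with an estimated correlation). The 2 were S100a9 and Camp, which had 0 counts at 60 h and stood at 0.996 ± 0.440 and 0.934 ± 0.159 CPM (SD, n = 2) with ACs, beside 5.14 and 1.48 CPM in ACs alone. Compared with the expected mixture, 0 of the 10 passed in edgeR in either direction, also at an unadjusted p of 0.05 (camera adjusted p = 0.252). The call of Gata6 was lost without 60 h replicate 2 of experiment 2 or either 60 h + ACs library. Klf4, Axl and Tlr9 did not pass the test, with changes of 0.04 ± 0.25, -0.23 ± 0.14 and -0.48 ± 1.09.

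Beyond mixing, 259 genes rose and 340 fell at 60 h. Of these, 258 rises and 211 falls also passed against the expected mixture. The largest rises were those of Lif, an interleukin-6 family cytokine gene (chromosome 11, 4257557 to 4272514), at 6.92 ± 0.49, Il1b, the costimulatory ligand gene Tnfsf9 at 4.40 ± 0.31 and Cxcl1. A Hgs record (ENSMUSG00000116045) rose by 6.27 ± 0.54, but it is uncertain, since it overlaps a further Hgs record on chromosome 11 that had a change of -1.36 ± 1.09. Falls were led by Inka1 at -2.44 ± 0.46, Klhl38 at -2.31 ± 0.50, Rgs2, a regulator of G protein signalling, at -2.17 ± 0.14, the apoptosis gene Bmf at -2.15 ± 0.17 and Bbs12 at -2.10 ± 0.62. Bbs12 lost its call without any 1 of the 4 libraries and Klhl38 without 60 h + ACs replicate 1. Over all genes, edgeR called 1655 higher and 750 lower with ACs, 1083 and 192 at least 2-fold. The count of lower genes was 198 with limma and 1348 with a replicate block, and it was 346 to 377 when any 1 of the 4 libraries of these groups was left out. The unexposed 60 h libraries carry an experiment label and the exposed ones do not, so the 2 sets may differ in more than ACs.

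**Figure D3:**
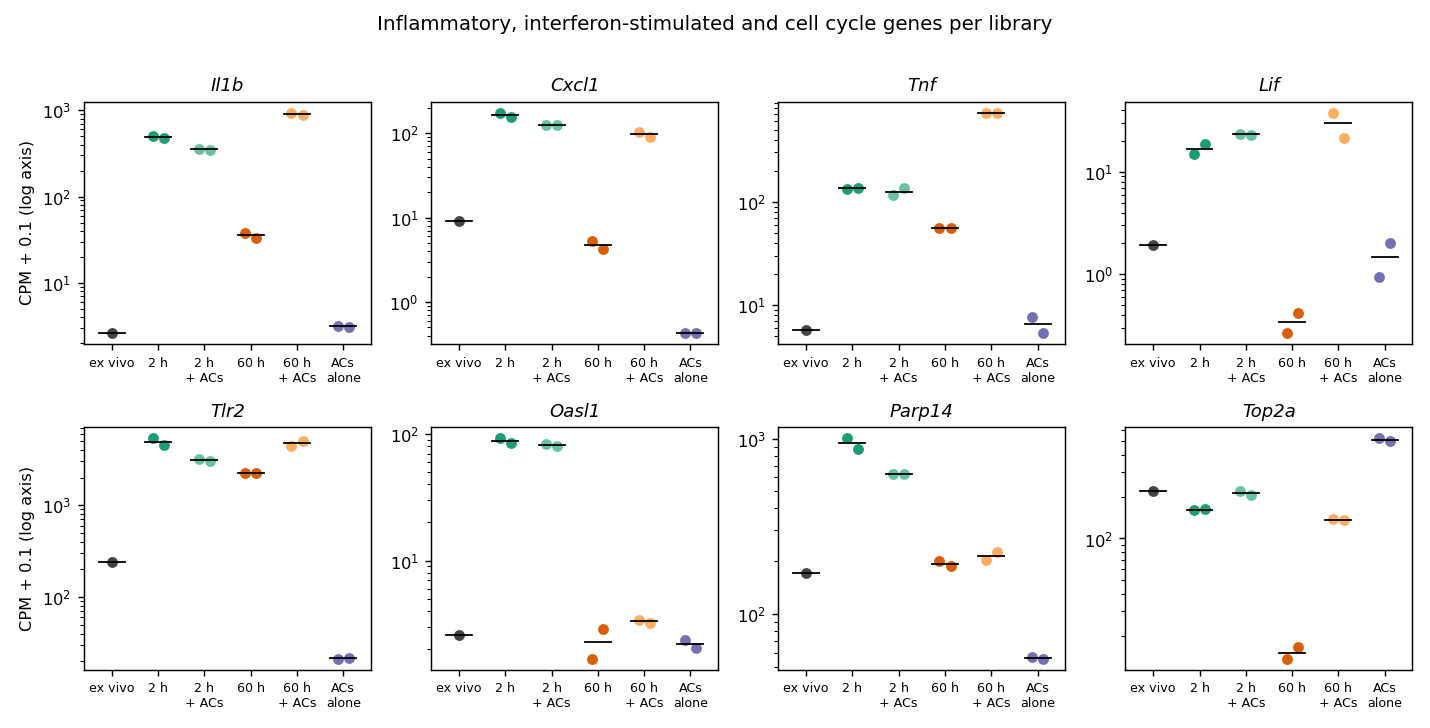
CPM + 0.1 on a log axis for 8 genes, with 1 point per library and a line at each group mean, for the same 6 groups. Il1b stood at 488 CPM at 2 h, 352 CPM at 2 h + ACs, 35.8 CPM at 60 h and 909 CPM at 60 h + ACs, whereas Oasl1 stood at 2.18 and 3.20 CPM at 60 h without and with ACs.

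The last comparison tested whether the change with ACs differed between 60 h and 2 h of culture. Larger and smaller here refer to signed log2 changes, not to their size. A larger change can thus follow a fall at 2 h, and a smaller one can be a deeper fall at 60 h. Inflammatory genes had the larger change at 60 h, 13 of 29 with 0 in the opposite direction, and 18 adjusted over the list alone (camera adjusted p = 8.32e-15). The log2 difference between the changes was 5.14 ± 0.17 for Il1b, 4.78 ± 0.22 for Cxcl1, 4.48 ± 0.20 for Cxcl2 and 4.42 ± 0.22 for Il1a. Of 25 feedback regulator genes, 9 had a larger change and 0 a smaller one, and 15 adjusted over the list alone (camera adjusted p = 1.67e-09), with Nfkbiz at 3.62 ± 0.19, Tnfaip3 at 1.90 ± 0.17, Dusp1 at 1.90 ± 0.20 and Nfkbia at 1.65 ± 0.16. Of 16 surface Toll-like receptor pathway genes, Tlr2, Cd14 and Irak2 differed, by 1.74 ± 0.17, 1.75 ± 0.31 and 1.29 ± 0.16, and 4 differed adjusted over the list alone. That list had a camera adjusted p = 0.0382 and an adjusted p = 0.388 in camera with an estimated correlation, and Traf6 had a difference of 0.57 ± 0.16 that did not pass. Cd14 lost its call without either 2 h + ACs library.

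Timd4 and Klf2 also differed, by 1.73 ± 0.28 and 1.77 ± 0.35, while Gata6, Klf4, Mertk, Axl and Tlr9 had differences of -0.60 ± 0.29, 0.47 ± 0.35, -0.11 ± 0.17, 0.25 ± 0.20 and 0.22 ± 1.57 that did not pass. By size, the differences were largest for Plat at 9.08 ± 1.1, the growth factor gene Ereg at 7.0 ± 1.14, Lif at 6.44 ± 0.59, Lipg at 5.82 ± 1.5 and the Hgs record at 5.8 ± 0.66. Plat and Lipg had 0 counts at 60 h without ACs, so their fitted differences are no bounds. Plat, Ereg and the Hgs record lost their calls with limma, and Lipg lost its call in 15 alternatives, among them the expected mixture and leaving out any 1 of 7 of the 8 libraries compared. They stood at 1.36 ± 0.66 and 0.209 ± 0.189 CPM (SD, n = 2) at 60 h with ACs. Ereg had 2 counts at 60 h without ACs, and its ratio with ACs was 227-fold (95% counting interval 62.4 to 1880). The signed change was lower at 60 h for Fam110b at -3.70 ± 0.71, Bmf at -3.15 ± 0.24 and the GTPase regulator gene Arhgap27 at -2.82 ± 0.24. It was also lower for Enc1 at -2.80 ± 0.21 and Lmln at -2.77 ± 0.48. Bmf fell with ACs at 60 h, so a lower change here is not always smaller in size. Lmln lost its call against the expected mixture and at 1.2 times the share, and Fam110b at 1.2 times the share. Over all genes, edgeR found 601 larger and 272 smaller changes, 398 and 212 of them by at least 2-fold. The excess of larger changes was not kept in every fit, with 421 larger and 411 smaller in fits of these groups alone, 322 and 289 with a replicate block and 416 and 446 without the AC-alone libraries. Against the expected mixture the counts were 428 and 96. By the least-squares weights the mixture shifts changes down at 2 h and up at 60 h, which tilts that split toward larger changes. With limma the counts were 125 and 66. Without 2 h + ACs replicate 1 they were 273 and 143, without 2 h + ACs replicate 2 258 and 141, and without 60 h + ACs replicate 2 366 and 138. Without 60 h replicate 1 of experiment 2 the larger changes numbered 365.

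**Figure D4:**
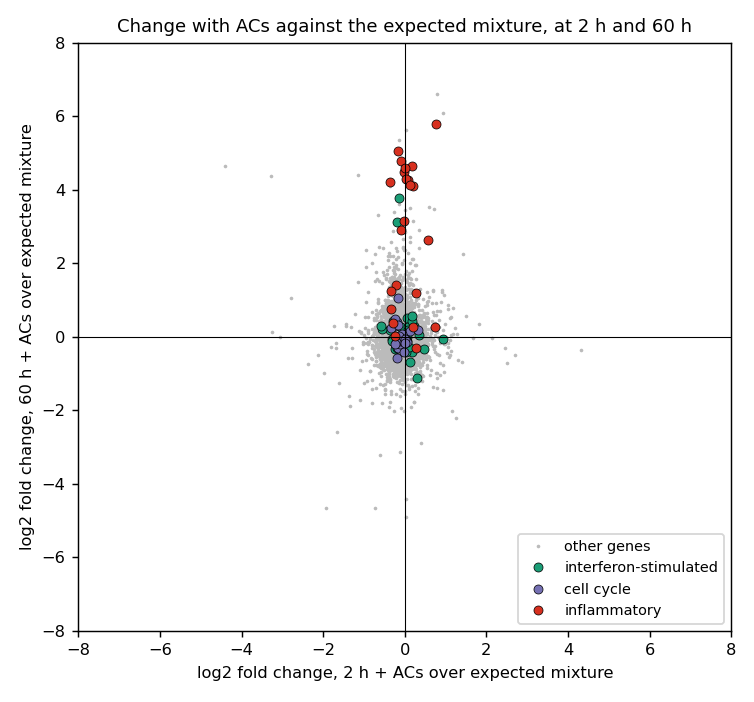
Log2 fold change of exposed libraries over the expected mixture of unexposed macrophage and AC RNA, at 2 h on the horizontal axis and 60 h on the vertical axis, for 9531 genes with a mean of at least 10 CPM in a macrophage group (13 lie outside the axes). Inflammatory genes such as Il1b, at -0.16 and 5.06, lie near 0 at 2 h and high at 60 h.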

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

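The tests of AC RNA, of a repeated response to culture, of handling, of a ceiling, of precision and of the expected mixture below were chosen only after the results were seen. The results here were picked out because the change with ACs differed between 60 h and 2 h of culture by edgeR's interaction test. By sign rather than size, the change was larger at 60 h for 601 genes and smaller for 272. That split was 421 and 411 in fits of these groups alone, 322 and 289 with a replicate block and 416 and 446 without the AC-alone libraries. Larger changes in this signed sense included 13 inflammatory, 9 feedback regulator, 14 cell cycle, 9 immediate early and stress and 3 surface Toll-like receptor genes. Of the cell cycle genes, 1 had a larger change against the expected mixture.

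On the log2 scale the differences of the named genes were 5.14 for Il1b, 4.78 for Cxcl1, 4.48 for Cxcl2 and 4.42 for Il1a, then 3.62 for Nfkbiz, 1.90 for Tnfaip3, 1.65 for Nfkbia and 1.90 for Dusp1. Tlr2, Cd14 and Irak2 differed by 1.74, 1.75 and 1.29, and Timd4 and Klf2 by 1.73 and 1.77. The largest were 9.08 for Plat, 7.0 for Ereg, 6.44 for Lif, 5.82 for Lipg and 5.8 for an uncertain Hgs record, where Plat and Lipg are fitted values against 0 counts. The opposite differences were -3.70 for Fam110b, -3.15 for Bmf, -2.82 for Arhgap27, -2.80 for Enc1 and -2.77 for Lmln.

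The inflammatory rise with ACs at 60 h was weighed first. AC RNA cannot account for it, since the excess of the 15 risen genes was a median of 104 times their level in ACs alone. A full repeat of the response to the first 2 h is argued against by the interferon-stimulated genes that rose then. Their median log2 change against the expected mixture at 60 h was 0.0464 (interquartile range -0.223 to 0.380), beside 1.88 over the first 2 h. For the 21 inflammatory genes that rose over the first 2 h, these medians were 3.44 and 4.21, so a partial repeat stays open. Another difference in handling or experiment between the exposed and unexposed 60 h libraries cannot be told apart from ACs, because 0 of the 60 h libraries carry the explicit treatment label for no ACs that the 2 h libraries have, and the unexposed ones carry an experiment label instead, and time away from the tissue remains an untested biological hypothesis.

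The near absence of rises beyond mixing at 2 h was weighed next. For the 15 genes with room to rise, a ceiling is argued against by a median log2 change against the expected mixture of 0.0226 at 2 h (interquartile range over genes -0.0776 to 0.163). By the least-squares weights, the mixture shifts this value down. Their median of 2.09 at 60 h is no contrast, since the genes were chosen among the rises at 60 h. The other 244 genes lacked such room, with 2 h levels nearer to the exposed 60 h level, so a ceiling cannot be told apart from a lack of response in them. Lower precision at 2 h cannot be judged from the median standard errors, which were 0.154 at both times. The 2 h and 60 h libraries shared a fit with a common spread per gene, which makes these errors nearly equal by design.

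The cell cycle rise with ACs at 60 h is consistent with AC RNA. The 21 risen genes had a median log2 change against the expected mixture of -0.0483 (interquartile range -0.15 to 0.192). Mki67 alone among them stood above it in edgeR, by 1.05, which leaves dividing macrophages in that gene open as an untested biological explanation.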

How the results depend on the processing

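The expected mixture, the fit without AC-alone libraries, the shares without TMM scaling the list tests in own groups with an estimated correlation and the alternatives for 60 h against 2 h were chosen only after the data were seen. Among named genes past the test, the calls kept in every alternative were 60 of 66 for 60 h culture, 32 of 33 for 2 h culture, 21 of 21 between them, 11 of 20 for ACs at 2 h, 28 of 36 for ACs at 60 h and 12 of 21 for the difference, with 0 reversed.

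With limma the counts were 1021 higher at 60 h, 1000 higher at 2 h, 1524 lower at 60 h than at 2 h, 17 lower with ACs at 2 h, 198 lower with ACs at 60 h, and 125 larger and 66 smaller changes. DESeq2 called 984 and 1255 lower with ACs at 2 h and 60 h and 511 smaller changes. With no filter 1039 were lower with ACs at 2 h, and 1023 changes were larger and 516 smaller. The length offset gave 1285 lower at 2 h, 157 and 337 lower with ACs, and 268 and 137 for the difference. Fits of the compared groups alone gave 1256 and 1089 at 2 h, 192 lower with ACs at 2 h and 411 smaller changes. Without AC-alone libraries 1342 were lower with ACs at 60 h and 446 changes smaller. Among genes lower in ACs alone, 3 and 211 rose with ACs, and 295 changes were larger and 58 smaller, with fewer genes counted. The cause of the other shifts was not tested.

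Rises beyond mixing at 2 h numbered 11 with DESeq2, 29 with no filter, 2 with the length offset, 15 with limma, and 7 against the expected mixture and at 0.8 times its share. Falls there numbered 13, 13 and 9 against the mixture at 1, 0.8 and 1.2 times the share. At 60 h the mixture gave 522, 492 and 638 rises, and 542 falls at 1.2 times the share. It gave 96, 107 and 81 smaller changes, where the shifts of the mixture given by the least-squares weights tilt the split toward larger changes. Shares were 21.1%, 23.2%, 21.2% and 21.4% by non-negative least squares and 12.9%, 14%, 18.3% and 18.1% without TMM scaling. List calls numbered 30 with an estimated correlation, 96 with fry in 1 direction and 123 in either direction, against 50, and 2 in fits of the compared groups alone with an estimated correlation. The lower shares without TMM scaling follow from the larger TMM scaling factors of ACs alone. The cause of the other shifts was not tested.

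Leaving out single libraries gave 1257 to 1284 higher and 1268 to 1402 lower at 60 h, 1887 to 2076 and 1729 to 1911 at 2 h, and 1832 to 2087 and 2151 to 2598 between them. It gave 687 to 976 and 72 to 645 with ACs at 2 h, 1161 to 1299 and 346 to 377 at 60 h, 258 to 690 and 138 to 383 for the difference, and 2 to 10 and 187 to 270 rises beyond mixing at 2 h and 60 h.

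The higher share of calls moved from 68.8% for the difference to 50.6%, 52.7% and 48.3% in fits of its groups, with the block and without AC-alone libraries, with median shifts of -0.162, -0.161 and -0.174. For ACs at 60 h it moved from 68.8% to 50.2% without AC-alone libraries and to 85.8% with limma. For ACs at 2 h it moved from 62.5% to 81.4% in its own groups, 97.9% with limma and 90.5% without 2 h + ACs replicate 2.

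Label numbers 1 and 2 share only a number. Same-numbered libraries correlated across genes at 0.145 (2 h without and with ACs), 0.266 (60 h) and -0.509 (2 h and 60 h + ACs). With the replicate block, 959 were higher and 338 lower with ACs at 2 h, 1688 and 1348 at 60 h, 322 and 289 for the difference, and 2072 and 1996 at 60 h against 2 h.

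Among named genes, values that reversed belong to genes that did not pass. Over all genes, 1 gene called after 2 h of culture was called in the opposite direction with limma. For Gata6, with ACs at 2 h, limma gave 0.0359. For Klf4, with ACs at 2 h, the length offset gave 0.0844 and limma 0.247. For Klf2, with ACs at 2 h, limma gave 0.172, its own groups 0.0533, the block 0.0435 and the fit without AC-alone libraries 0.0528, and leaving out single libraries gave -0.268 to 0.201. For Timd4, after 2 h of culture, leaving out single libraries gave -0.377 to 0.0192. For Klf4, with ACs at 60 h, RLE gave -0.0214, DESeq2 -0.0211, the length offset -0.0081 and the fit without AC-alone libraries -0.0549, with -0.229 to 0.352 when single libraries were left out. The cause was not tested.

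Not run were the fits without the experiment term, with experiment 2 alone, with all 4 of the 60 h libraries as reference and without the ex vivo library, since experiment 1 could not be joined. Depth and 2 libraries per group limit small changes.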

Other observations

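The tests of overlap with the response to culture and of experiment 1 were chosen only after the results were seen. Genes higher beyond mixing with ACs at 60 h were largely genes that had also risen over the first 2 h of culture. The overlap was 210 of 259, while 8 of the 259 had fallen over those 2 h. Independent draws from all 17578 genes would share 29.8 with the rises. That figure is too low, because genes higher in ACs alone cannot be rises beyond mixing. Above the expected mixture the overlap was 387 of 522, against 60.1 counted over all genes in the same way. The 2 comparisons share no library, but the overlap of 210 rests on 1 fit with a common spread per gene. Of all 2025 genes that rose over the first 2 h, 387 (19.1%) stood above the mixture at 60 h. Among them were 14 of 21 inflammatory genes and 3 of 23 interferon-stimulated genes, so the inflammatory genes stand apart from the whole set more than the interferon-stimulated genes do. Fisher's exact test between these lists, two-sided, gave p = 4.78e-04, though genes are not independent.

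In experiment 1, whose targets could be named for few genes, 258 genes were compared without a test. The 608 named targets stand for 604 genes, so nearly every gene is measured there by 1 target. That target was set against the sum of all transcripts of the gene in the fit, so the 2 values are unlike measures. Of 58 of them called at 60 h in the fit, 47 (81%) moved in the same direction, with 22 of 25 rises and 25 of 33 falls. The correlation across genes was 0.256 (Pearson) and 0.361 (Spearman).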
